A study of Arabidopsis thaliana with 90 samples.

How the data were processed

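The series held 90 libraries in 30 groups from 9-day-old Arabidopsis seedlings, and 30 libraries of the wild type, 3 for each of 10 features, were analysed as peak lists together with 11 lists of regions given for the whole series. Per the labels, seedlings grew in continuous white light and replicates were biological. The WDR5A-HA libraries were made with beads against the HA tag, and their genotype was given as Col-0 per the labels. Libraries of mutant plants, inputs and control precipitations were not analysed here, so no genotypes were compared and no background from control precipitations was set beside the values.

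Per the submitters' processing notes, reads were trimmed with fastp, aligned to TAIR10 with Bowtie2 2.3.3, and peaks were called per library with MACS2 2.2.5. The control used for peak calling is not given in the sources used here. The deposited library lists give for each peak its start, end and summit positions, a score, a fold enrichment (ratio over the caller's background), −log10 p and −log10 q. The score deposited by the authors equals 10 times −log10 q, and for E2FA 10 times −log10 p, as tested on the files. E2FA peaks reached a p-value of 0.01 and those of all other features a q-value of 0.05 in the deposited lists, so the E2FA lists were the more lenient. The deposited lists for the whole series hold positions only. For 9 features these were the merged regions shared by at least 2 libraries, matching for at least 99.97% of regions by start and end. For WDR5A-HA, 17439 of 17441 regions instead had the bounds of the merged peaks of libraries 1 and 2. The TBP list was identified by its name alone. Read totals are not part of peak lists, so depth per library was unknown, and no limit that depends on depth was computed.

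Gene positions came from the RefSeq table of assembly TAIR10.1, used for gene identity and gene bounds and not printed. Whether it shares the coordinate frame of the TAIR10 peaks was checked: 96.9% of 15948 H3K4me3 summits of replicate 1 lay in genes, against 67.8% to 69.9% after moving genes by 1000 or 2000 bp. The share per chromosome bin was 80.8% to 100.0% with a median of 97.1% over 110 bins. The table gives no strand. The windows planned around transcription start sites were therefore replaced by 500 bp to either side of both gene ends for BTE1, E2FA, WDR5A-HA, TBP, H3K4me2, H3K4me3 and H2A.Z. For total Pol II, Ser5P, Ser2P and H3K4me1 the gene body was used. A gene was called when a peak covered at least 1 bp of its window in all 3 libraries, so neighbouring genes can share a peak. In simulated data, 0.54 other genes were called per seeded gene.

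For positions along genes, a gene was oriented when its highest-scoring H3K4me3 summit lay at a relative position below 0.4 in all 3 libraries, or above 0.6 in all 3, and that end was taken as the 5′ end, which oriented 13561 genes. H2A.Z summits oriented 16683 genes and were used where H3K4me3 was compared, and for 99.1% of the 12103 genes oriented by both the direction was the same.

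Co-occupancy of genes was tested with Fisher's exact test, two-sided, over 27444 nuclear protein-coding genes, with Benjamini-Hochberg adjustment over 27 pairs of features. Genes are not independent replicates, so odds ratios of single library pairs were computed to show the spread between libraries. Single libraries call more genes than the rule of 3 libraries, so this spread need not contain the odds ratio of the rule. P-values of the largest tables lay below the smallest number held and are not printed. Overlap of peaks was compared with 1000 circular shifts within chromosomes and with 200 moves to random gene ends, one-sided. Positions were compared with exact permutation tests, two-sided, over 3 against 3 libraries. The 13 gene lists, 364 genes in all, were each tested against all other genes with adjustment over the lists, and exact Clopper-Pearson 95% intervals were computed, which cover counting error only. All genes of the lists were found in the table by identifier.

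The tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. That rule named the 10 genes with the best mean rank of peak score for BTE1, 10 for E2FA and 5 for WDR5A-HA, the 4 best-ranked called members of each list past an adjusted p of 0.05, and all DREAM subunit genes. List members of WDR5A-HA were named for the lists where only WDR5A-HA passed. Alternatives covered peak score, overlap, window width, number of libraries, the lists for the whole series, gene length, background genes and leaving out each replicate. The search for E2F motifs was not run, since it needs the genome sequence. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and gene calls, co-occupancy, peak shifts, gene orientation and the exact tests were tested on simulated data, where a planted odds ratio of 3.0 was recovered as 3.02.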

Results

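The data were peak lists from chromatin immunoprecipitation sequencing of 9-day-old Arabidopsis thaliana seedlings of the wild type. The 10 features measured were the DREAM-complex protein BTE1, the transcription factor E2FA, the tagged COMPASS subunit WDR5A-HA, total RNA polymerase II (Pol II), its Ser5-phosphorylated and Ser2-phosphorylated forms, H3K4me1, H3K4me2, H3K4me3 and the histone variant H2A.Z, each in 3 biological replicates. A single list of regions for the TATA-binding protein TBP had no replicates. BTE1 had 1705 ± 293 peaks per library and E2FA 4664 ± 1134 (mean ± SD, n = 3). WDR5A-HA had 17452 ± 676 peaks, total Pol II 11543 ± 461, Ser5P 13218 ± 1071 and Ser2P 11116 ± 596 (SD, n = 3). H3K4me1 had 14447 ± 61.1 peaks, H3K4me2 18740 ± 427, H3K4me3 16037 ± 113 and H2A.Z 26322 ± 646 (SD, n = 3). The share of peaks found in both other libraries was 97.2% ± 0.843 for H3K4me3, 82.6% ± 4.57 for WDR5A-HA, 61.8% ± 11.05 for BTE1 and 37.1% ± 9.04 for E2FA (SD, n = 3). Peak lists hold no read totals, so sequencing depth was unknown.

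Of 27444 nuclear protein-coding genes, BTE1 was called at 1436 genes in all 3 libraries and E2FA at 2308. WDR5A-HA was called at 13989 genes, total Pol II at 11190, Ser5P at 10874 and Ser2P at 11579. H3K4me1 was called at 10023 genes, H3K4me2 at 15910, H3K4me3 at 17352 and H2A.Z at 21593, and TBP regions touched 15607 genes. The E2FA count rested on replicate 2, the library with the fewest peaks, and reached 3882 genes without it.

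**Figure D1:**
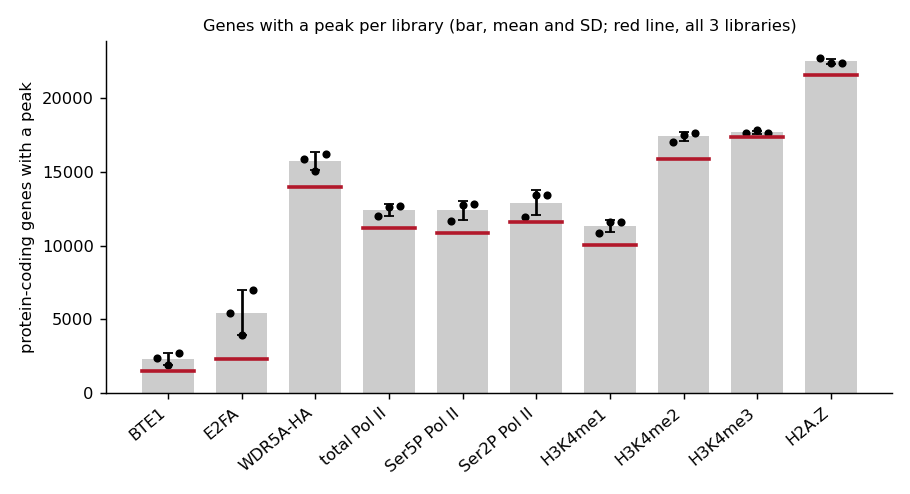
Number of protein-coding genes carrying each feature, per library and in all 3 libraries. BTE1 (1436 genes) and E2FA (2308 genes) occupied far fewer genes than WDR5A-HA (13989 genes).

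Most BTE1 genes also carried E2FA, which addressed whether BTE1 sits with the E2F arm of the DREAM complex, a repressor of cell cycle genes. E2FA was called at 1103 of the 1436 BTE1 genes, 76.8%, against 4.63% of other genes (odds ratio 68.2, 95% interval 59.5 to 78.1). Conversely, 47.8% of E2FA genes carried BTE1, and 1205 of them did not. Independent placement would give 121 shared genes. The odds ratio lay between 14.8 and 23.4 over the 9 pairs of single libraries, and was 33.6 without replicate 2 of each feature. At the level of peaks, 68.3% ± 5.79 of BTE1 peaks overlapped an E2FA peak (SD over 9 library pairs), against 3.52% after shifting peaks along the chromosomes (permutation p 0.001, one-sided, the smallest possible) and 8.11% after moving them to random gene ends. In turn, 25.5% ± 4.49 of E2FA peaks overlapped a BTE1 peak, against 1.3% after shifting. Sharing rose with peak score: with the peaks of each library split into 4 equal groups by score, 56.2% ± 4.21 of the lowest-scoring group of BTE1 peaks overlapped an E2FA peak of any library, and 98.5% ± 0.445 of the highest-scoring group (SD, n = 3). For E2FA peaks overlapping BTE1, these shares were 7.35% ± 0.731 and 78.6% ± 7.00 (SD, n = 3).

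The 10 genes with the highest-ranked BTE1 peaks included MCM7, RNR1, CDT1A and RPA3A. The peak between MCM7 (AT4G02060), a helicase subunit, and its neighbour STP7 (AT4G02050), on chromosome 4 from 900970 to 902329 in TAIR10, had a fold enrichment of 24.4 ± 2.24 (SD, n = 3). At RNR1 (AT2G21790), the large subunit of ribonucleotide reductase, BTE1 fold enrichment was 27.7 ± 13.04 (chromosome 2, 9292905 to 9294379), with replicate 2 at 42.8. CDT1A (AT2G31270), a replication licensing factor, had 26.2 ± 4.59 (chromosome 2, 13328279 to 13329712), and AT3G23740 had 22.9 ± 1.963. A peak shared by COP9 (AT4G14110) and AT4G14120 had 24.0 ± 8.61, and one shared by AT3G52620, AT3G52630 (RPA3A) and AT3G52640 had 21.4 ± 6.74. All of these genes were also called for E2FA in all 3 libraries. The strongest E2FA peaks included those at MCM5 (AT2G07690), with a fold of 27.5 ± 4.34, UBA2A (AT3G56860) and AT3G56870, sharing a peak of 23.8 ± 4.22, COP9 and AT4G14120 (27.5 ± 9.73), RNR1 (21.6 ± 4.90) and AT3G23740 (20.9 ± 7.86). AT5G52950 and AT5G52960 shared an E2FA peak of 22.6 ± 4.32, and AT5G67090 had 18.1 ± 2.57 (SD, n = 3 throughout).

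BTE1 was enriched at 9 of 13 gene lists fixed in advance and E2FA at 8, and DNA replication genes stood highest for both. BTE1 was called at 48 of 54 DNA replication genes, 88.9% (exact 95% interval 77.4 to 95.8), against 5.07% of other genes (Fisher's exact adjusted p 3.67e-54). E2FA was also called at 48 of them (adjusted p 3.17e-44), and 47 carried both. Of 28 histone genes, 16 carried BTE1 and 14 carried E2FA (adjusted p 3.17e-13 and 3.58e-08). BTE1 was called at 9 of 15 genes of chromatin replication and DNA methylation, and E2FA at 11 (adjusted p 2.80e-08 and 9.39e-09). For DNA repair and checkpoint genes the counts were 11 and 12 of 25 (adjusted p 3.79e-08 and 5.81e-07), and for mitotic genes 16 and 14 of 37 (adjusted p 5.71e-11 and 1.76e-06). At mitotic genes the E2FA call ended with the H3K4me3-marked 5′ end alone (16.7% of the members oriented by H3K4me3, adjusted p 0.381). G1/S regulators gave 9 and 10 of 27 (adjusted p 1.06e-05 and 7.14e-05). Transcription elongation and COMPASS genes gave 6 and 7 of 33 (adjusted p 0.00962 and 0.0293), and neither call held with peaks required in at least 2 libraries (adjusted p 0.0543 and 0.0800) or among genes with total Pol II or Ser5P (adjusted p 0.384 and 0.771). Among the latter genes the DNA repair calls also ended, at 16.7% each (adjusted p 0.373 for BTE1 and 0.771 for E2FA). That of G1/S regulators ended for E2FA (25.0%, adjusted p 0.211), and 7 and 5 lists stayed enriched for BTE1 and E2FA. Of the repair genes only MSH6, ATM, ATR, KU70, MRE11 and RAD50 remained there, so a lost call need not mean that enrichment was absent. BTE1 was further called at 5 of 13 constitutively expressed reference genes (adjusted p 0.000572), where E2FA was called at 1 (adjusted p 1.0), or at 23.1% without replicate 2 (adjusted p 0.448). Photosynthesis genes (2 and 3 of 42), cytosolic ribosomal protein genes (2 and 1 of 22) and light signalling and clock genes (2 and 2 of 20) were not enriched for either. Without replicate 2, the E2FA shares of these lists were 19.0%, 18.2% and 30.0%. None of 29 seed and floral genes carried BTE1 or E2FA, which allows a share of up to 11.9% by the exact 95% interval. For E2FA this absence passed the threshold with peaks in at least 2 libraries (adjusted p 0.0162), with the lists for the whole series (adjusted p 0.0279) and without replicate 2 (adjusted p 0.0447).

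Among the list members with the highest-ranked BTE1 peaks, RPA1B (AT5G08020) had a fold enrichment of 22.8 ± 3.38, and the DNA methyltransferase genes MET1 (AT5G49160) and CMT3 (AT1G69770) had 17.1 ± 4.40 and 11.8 ± 1.03. The chromatin assembly factor genes FAS1 (AT1G65470) and FAS2 (AT5G64630) had 14.96 ± 5.12 and 9.26 ± 0.344. Repair genes reached similar values, with BARD1 (AT1G04020) at 20.25 ± 5.43, MSH6 (AT4G02070) at 17.9 ± 2.26, BRCA1 (AT4G21070) at 17.5 ± 1.87 and TSK (AT3G18730) at 11.9 ± 3.81. Among mitotic genes, CDKB1;1 (AT3G54180) had 8.46 ± 2.86, POK2 (AT3G19050) 8.04 ± 2.62, CYCA1;1 (AT1G44110) 7.53 ± 0.542 and TPX2 (AT1G03780) 5.69 ± 0.648. The D-type cyclin genes CYCD4;1 (AT5G65420), CYCD4;2 (AT5G10440), CYCD5;1 (AT4G37630) and CYCD1;1 (AT1G70210) had folds of 15.6 ± 2.19, 11.8 ± 1.99, 8.81 ± 1.08 and 5.55 ± 0.862. Histone genes HTA13 (AT3G20670) and HTR2 (AT1G09200) had 11.01 ± 2.16 and 7.41 ± 1.41, and HTR13 (AT5G10390) and HTR9 (AT5G10400) shared a peak of 9.63 ± 1.75. The H3K4 methyltransferase gene ATX1 (AT2G31650) had 16.4 ± 4.23, TBP1 (AT3G13445) 12.5 ± 2.77, SPT5-1 (AT2G34210) 11.7 ± 2.16 and TBP2 (AT1G55520) 11.4 ± 2.33. The 4 best-ranked reference genes ranged from 3.98 ± 0.583 at TUB2 (AT5G62690) to 8.34 ± 1.71 at PP2AA3 (AT1G13320), with ACT2 (AT3G18780) and ACT8 (AT1G49240) between them (SD, n = 3 throughout).

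BTE1 and E2FA also occupied genes of the DREAM complex itself. BTE1 was called at 11 of 20 subunit genes (adjusted p 2.73e-09, Fisher's exact test) and E2FA at 12 (adjusted p 3.50e-08). Both were called in all 3 libraries at TCX5, TCX6, TCX3, TCX2, TCX7, ALY1, E2FA, E2FC, DPA and RBR1. E2FB had BTE1 peaks in 3 libraries and E2FA peaks in 2, while ALY2 and MSI1 had E2FA peaks in 3 and BTE1 peaks in 1. TSO1 and MYB3R3 had neither in any library, and MYB3R1 and MYB3R4 had each in 1 library. MYB3R5 had E2FA peaks in 1 library, and ALY3 and DPB in 2, without BTE1 peaks. BTE1 fold enrichment was 8.09 ± 0.221 at TCX2 (AT4G14770), 6.44 ± 0.246 at E2FC (AT1G47870), 6.36 ± 0.364 at E2FA (AT2G36010) and 5.80 ± 1.28 at RBR1 (AT3G12280) (SD, n = 3).

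**Figure D2:**
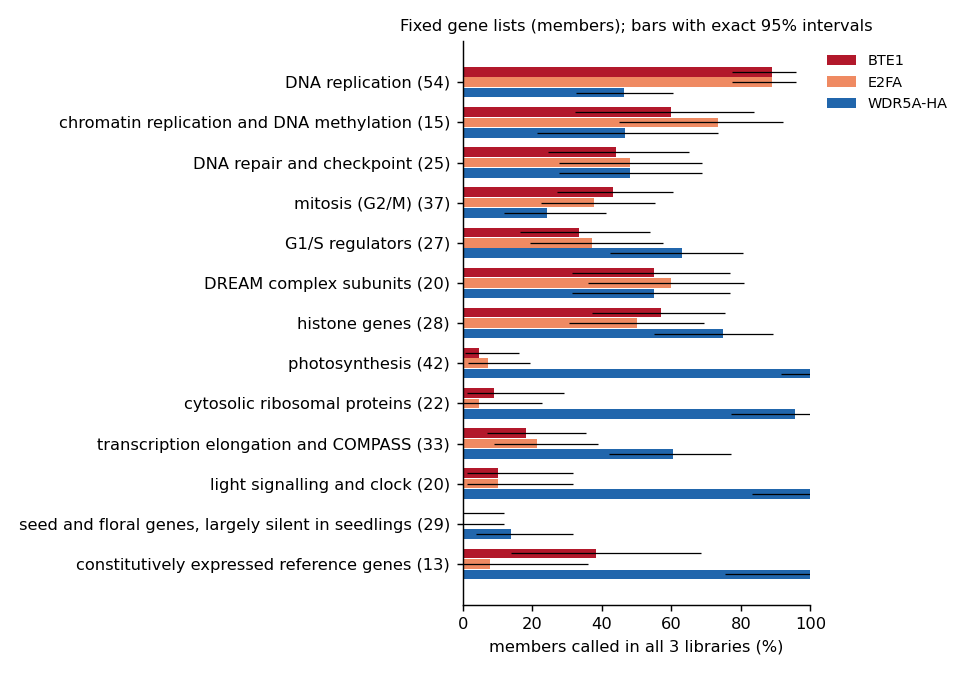
Percent of the members of each fixed gene list called for BTE1, E2FA and WDR5A-HA in all 3 libraries, with exact 95% intervals and the list size in brackets. DNA replication genes were called for BTE1 and E2FA at 88.9%, and all 42 photosynthesis genes carried WDR5A-HA.

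WDR5A-HA, a subunit of the complexes that methylate H3K4, marked a wide set of genes that included 871 of the 1436 BTE1 genes. That share, 60.7%, stood against 50.4% of other genes (odds ratio 1.51, 95% interval 1.36 to 1.69, Fisher's exact adjusted p 5.50e-14), and the 9 pairs of single libraries gave odds ratios of 1.62 to 2.33. This association held against all genes and not in narrower sets. The odds ratio was 1.05 (adjusted p 0.696) among genes with total Pol II or Ser5P. It passed the threshold in the opposite direction among H3K4me3-marked genes (0.746, adjusted p 0.00014) and with the H3K4me3-marked 5′ end alone (0.830, adjusted p 0.0194). H3K4me3-marked genes here and below are the 13561 oriented by an H3K4me3 summit, not all 17352 called for H3K4me3. For E2FA, 1486 of 2308 genes carried WDR5A-HA, 64.4% against 49.7% (odds ratio 1.83, adjusted p 1.03e-41, and 2.76 without replicate 2). The E2FA odds ratio was 1.105 (adjusted p 0.26) among genes with total Pol II or Ser5P and 0.969 (adjusted p 0.67) among H3K4me3-marked genes. WDR5A-HA covered 52.8% ± 3.88 of BTE1 peaks and 50.1% ± 8.65 of E2FA peaks (SD over 9 library pairs), against 33.8% and 30.6% for peaks moved to random gene ends (permutation p 0.005, one-sided, the smallest possible). WDR5A-HA overlapped 59.8% ± 9.57 of the lowest-scoring group of BTE1 peaks and 59.5% ± 1.25 of the highest (SD, n = 3), rising in libraries 1 and 2 and falling in library 3. The median fold of BTE1 peaks with WDR5A-HA was lower than that of peaks without in all 3 libraries, 3.58 ± 0.625 against 4.02 ± 0.399 (SD, n = 3), untested.

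WDR5A-HA occupied every photosynthesis gene tested, 42 of 42 (Fisher's exact adjusted p 7.70e-12), every light signalling and clock gene, 20 of 20 (adjusted p 1.32e-05), all 13 reference genes (adjusted p 0.000652) and 21 of 22 ribosomal protein genes (adjusted p 5.06e-05). It was called at 21 of 28 histone genes (adjusted p 0.0241), a call that ended with wider windows (adjusted p 0.104). It was called less often than at other genes at the mitotic list, 9 of 37 (adjusted p 0.00309, and 0.168 with peaks above the median score), and at seed and floral genes, 4 of 29 (adjusted p 0.000148). Both of these calls ended among genes with total Pol II or Ser5P (adjusted p 0.0788 and 0.431). Few mitotic genes remained there, and of the seed and floral genes only AP1 and SHP1. That test therefore had too few members to decide, and a lost call need not mean that the lower share was absent. No difference was detected for DNA replication genes (25 of 54), chromatin replication genes (7 of 15), DNA repair genes (12 of 25), G1/S regulators (17 of 27), DREAM subunit genes (11 of 20) and elongation and COMPASS genes (20 of 33). With the H3K4me3-marked 5′ end alone, a test chosen after the data were seen, WDR5A-HA was called less often than at other such genes for DNA replication (32.3%, adjusted p 0.00951), chromatin replication (20.0%, adjusted p 0.0417) and DNA repair (17.6%, adjusted p 0.00301). These are shares of the list members oriented by an H3K4me3 summit, fewer than the full lists. They used 1 gene end, so they cannot be set against the counts above. Against genes with total Pol II or Ser5P alone, 1 list stayed enriched for WDR5A-HA instead of 5. Ribosomal, light signalling and reference genes lost their calls there while at 100% (Fisher's exact adjusted p 0.0788, 0.0957 and 0.245). WDR5A-HA was called at 82.4% of total Pol II genes and 85.3% of Ser5P genes, so short lists had little room to pass.

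The highest-ranked WDR5A-HA peaks lay at RAP2.4 (AT1G78080), with a fold enrichment of 7.48 ± 0.429 on chromosome 1 from 29364133 to 29367659, TPR3 (AT5G27030, 8.66 ± 0.514), HB5 (AT5G65310, 9.21 ± 0.680), and CRK26 (AT4G38830) with AT4G38840, sharing a peak of 8.60 ± 0.468. TPR3, encoding a TOPLESS-related corepressor, was the only one of these called for BTE1. Photosynthesis genes with high WDR5A-HA folds were RBCS3B (AT5G38410, 7.29 ± 0.318), RBCS1A (AT1G67090, 7.11 ± 0.689), LHCB1.5 (AT2G34420, 5.59 ± 0.108) and LHCB1.3 (AT1G29930, 4.99 ± 0.483). The 4 best-ranked ribosomal protein genes ranged from 5.03 ± 0.174 at RPS18A (AT1G22780) to 5.75 ± 0.353 at RPL24A (AT2G36620), with RPL4A and RPL4D between them. The clock gene PRR9 (AT2G46790) had 7.86 ± 0.752, CCA1 (AT2G46830) 5.64 ± 0.345, and the light signalling genes PIF5 (AT3G59060) and PIF4 (AT2G43010) 5.59 ± 0.191 and 5.40 ± 0.152. The 4 seed and floral genes called were SEP3 (AT1G24260, 4.76 ± 0.457), AP1 (AT1G69120, 4.60 ± 0.221), AP3 (AT3G54340, 2.51 ± 0.192) and OLEO1 (AT4G25140, 2.45 ± 0.22) (SD, n = 3 throughout).

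BTE1 genes carried H2A.Z and H3K4me2 far more often than other genes, while the result for Pol II depended on the gene rule. H2A.Z was called at 97.8% of BTE1 genes against 77.6% of others (odds ratio 12.6, Fisher's exact adjusted p 3.58e-106), and H3K4me2 at 91.2% against 56.1% (odds ratio 8.12, adjusted p 2.04e-181). H3K4me3 stood at 82.4% against 62.2% (odds ratio 2.85, adjusted p 1.84e-59), H3K4me1 at 52.9% against 35.6% (2.03, adjusted p 4.36e-38) and TBP at 63.6% against 56.5% (1.35, adjusted p 1.07e-07). Total Pol II was called at 37.8% of BTE1 genes against 40.9% (odds ratio 0.877, adjusted p 0.0206), Ser5P at 38.1% against 39.7% (0.934, adjusted p 0.233) and Ser2P at 39.8% against 42.3% (0.902, adjusted p 0.0685). The 9 pairs of single libraries gave 0.960 to 1.18 for total Pol II, 1.09 to 1.33 for Ser5P and 1.04 to 1.23 for Ser2P. The total Pol II call ended without replicate 2 (odds ratio 0.970, adjusted p 0.567). Over all alternatives the total Pol II value ranged from 0.493 to 1.006, the highest with wider windows (adjusted p 0.899). The Ser5P value ranged from 0.496 to 1.18 with the gene rule, past the threshold at both ends. Over gene length strata all 3 forms were called less often at BTE1 genes (0.733, 0.736 and 0.705, adjusted p 2.39e-08, 2.85e-08 and 2.44e-10). With peaks above the median score, the H3K4me3 and H3K4me1 calls ended (odds ratios 1.04 and 1.03, adjusted p 0.647 and 0.798), and the TBP odds ratio fell to 0.670 among H3K4me3-marked genes. The TBP call ended over gene length strata (1.09, adjusted p 0.121) and among genes with total Pol II or Ser5P (1.15, adjusted p 0.518), where the H3K4me1 call ended as well (1.16, adjusted p 0.084). The H2A.Z and H3K4me2 odds ratios were at least 3.73 and 4.59 under every alternative run.

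E2FA genes had the same marks, with odds ratios of 7.08 for H2A.Z (Fisher's exact adjusted p 2.74e-133), 5.18 for H3K4me2 (adjusted p 1.15e-210), 3.19 for H3K4me3 (adjusted p 1.94e-110), 2.38 for H3K4me1 (adjusted p 2.36e-86) and 1.86 for TBP (adjusted p 8.13e-42). Their odds ratios for Pol II were 1.15 for total Pol II (adjusted p 0.00203), 1.32 for Ser5P and 1.28 for Ser2P. These rose to 1.98, 2.29 and 2.14 without replicate 2, as TBP did to 2.96, and turned below 1 with 50% coverage (0.856, 0.921 and 0.944) and among H3K4me3-marked genes (0.660, 0.755 and 0.746). The total Pol II value with 50% coverage (adjusted p 0.00617) passed the threshold in the opposite direction. So did all 3 values among H3K4me3-marked genes (adjusted p at most 7.37e-07). Over gene length strata no difference was detected (0.948, 1.03 and 0.995). The TBP call ended among H3K4me3-marked genes (1.00, adjusted p 1.0). WDR5A-HA genes carried every feature more often than other genes, led by TBP (87.7% against 24.8%, odds ratio 21.7), H3K4me3 (90.3% against 35.1%, 17.1), Ser5P (66.3% against 11.9%, 14.5) and total Pol II (65.9% against 14.6%, 11.3). Ser2P (8.23), H2A.Z (6.67), H3K4me2 (5.15) and H3K4me1 (4.02) followed. Of these, H2A.Z, H3K4me2 and H3K4me1 turned below 1 among H3K4me3-marked genes (0.683, 0.758 and 0.949), H2A.Z and H3K4me2 past the threshold. TBP windows took in both gene ends. Midpoints of TBP regions in oriented genes lay in the last of 5 equal parts (36.7%) about as often as in the first (36.0%). A TBP call therefore need not mark a promoter. Genes with BTE1 and E2FA together carried total Pol II less often (35.1%) than genes with BTE1 alone (46.8%, odds ratio 1.63, Fisher's exact adjusted p 0.000184) or E2FA alone (51.9%, odds ratio 1.99, adjusted p 1.83e-15). These classes depended on the rule of 3 libraries, since 78.1% of the genes with BTE1 alone had an E2FA peak in at least 1 library. No other gene rule was run for this comparison. The median BTE1 fold was 3.85 at genes with BTE1 alone and 5.505 at genes with both. E2FA windows took in both gene ends. In the last of 5 equal parts of genes 59.35% ± 17.9 of E2FA summits lay in total Pol II peaks, against 18.4% ± 6.08 in the first (SD, n = 3). Neither difference was taken into account here.

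**Figure D3:**
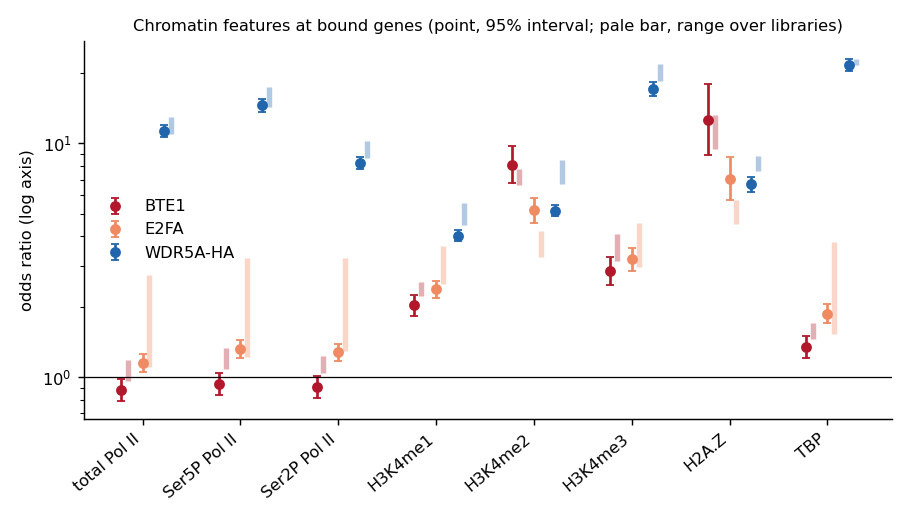
Odds ratios, on a log axis, between genes called for BTE1, E2FA or WDR5A-HA and genes called for Pol II forms, H3K4 methylation, H2A.Z and TBP. Points have 95% intervals, and pale bars give the range over single libraries. BTE1 with H2A.Z stood at 12.6, and BTE1 with total Pol II at 0.877.

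Among genes with Ser5P, the initiating form of Pol II, those bound by BTE1 carried the elongating form Ser2P less often, which addressed whether BTE1 genes differ in productive elongation. Ser2P was called at 467 of 547 such BTE1 genes, 85.4%, against 9295 of 10327 others, 90.0% (odds ratio 0.648, 95% interval 0.507 to 0.829, Fisher's exact p 0.000839). The odds ratio was below 1 in 9 of 9 combinations of libraries, from 0.596 to 0.745. Each combination joined a BTE1 library with Ser5P and Ser2P libraries of the same replicate number, and no others were run. The difference did not hold under other gene rules: the odds ratio was 1.31 (p 0.0931) when the peak summit had to lie in the gene window, and 0.970 (p 0.829) when total Pol II replaced Ser5P. Lower Ser2P was not particular to BTE1, since WDR5A-HA genes had an odds ratio of 0.690 (Fisher's exact adjusted p 0.000716) and E2FA genes 0.776 (adjusted p 0.0199). Genes with both BTE1 and E2FA had 0.596 (adjusted p 0.00122), genes with BTE1 alone 0.852 (adjusted p 0.627) and genes with E2FA alone 0.961 (adjusted p 0.741), and the difference between these classes was not tested.

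BTE1 summits inside genes sat at gene starts, at a median of 149 ± 5.97 bp inside the 5′ end (SD, n = 3). Positions cover only summits inside genes oriented by H3K4me3, 852 ± 187 per library for BTE1 and 2270 ± 552 for E2FA (SD, n = 3). With genes divided into 5 equal parts, 86.1% ± 1.011 of these BTE1 summits lay in the first part (SD, n = 3). WDR5A-HA summits were split, 62.6% ± 0.563 in the first part and 20.5% ± 0.380 in the last part, and E2FA summits likewise, 48.2% ± 5.90 and 27.7% ± 10.6 (SD, n = 3). Ser5P and Ser2P summits both lay toward the 3′ end, at median relative positions of 0.820 ± 0.0258 and 0.852 ± 0.0129, from 0 at the 5′ end to 1 at the 3′ end (difference −0.0322, exact permutation p 0.2, n = 3, two-sided, smallest possible 0.1). Leaving out each replicate in turn gave differences of −0.0515 to −0.0188. In replicate 1 Ser5P lay further toward the 3′ end than Ser2P (0.845 against 0.8385). Ser5P had more summits in the first part, 24.7% ± 1.33 against 11.6% ± 0.413 for Ser2P (exact permutation p 0.1, n = 3), a measure chosen after the data were seen. Total Pol II summits had a median of 0.701 ± 0.0363 (SD, n = 3).

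The 3 methylation states of H3K4 lay in order along genes. In genes oriented by H2A.Z, H3K4me3 summits had a median relative position of 0.132 ± 0.0008, H3K4me2 0.217 ± 0.0027 and H3K4me1 0.492 ± 0.0032 (SD, n = 3). H3K4me3 lay −0.360 from H3K4me1 and −0.0853 from H3K4me2, with no overlap between libraries (exact permutation p 0.1 for each, n = 3, the smallest possible, adjusted 0.15). The first of the 5 parts of genes held 76.6% ± 0.345 of H3K4me3 summits, 45.1% ± 0.789 of H3K4me2 summits and 3.91% ± 0.0273 of H3K4me1 summits (SD, n = 3).

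**Figure D4:**
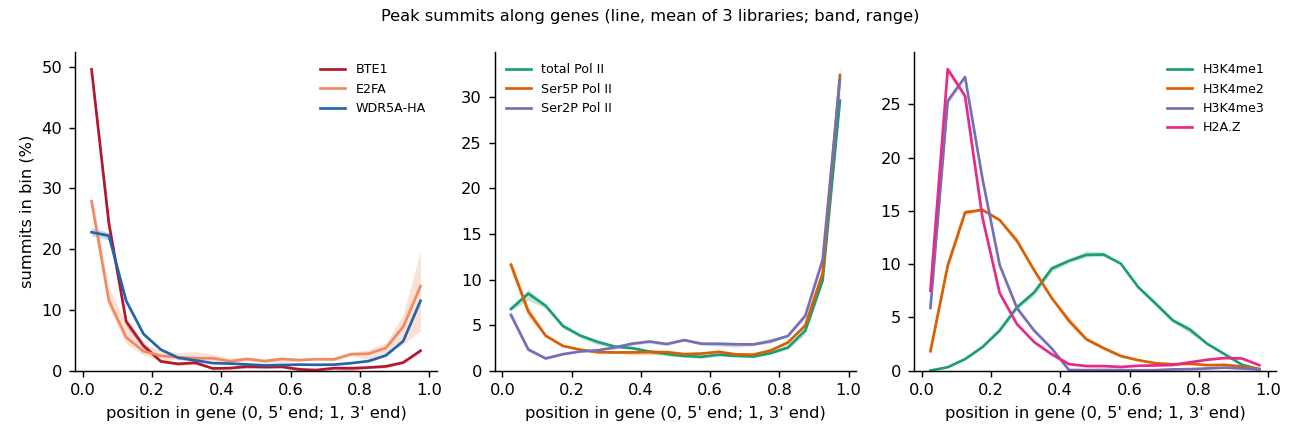
Distribution of peak summits along protein-coding genes from the 5′ end (0) to the 3′ end (1), with genes oriented by H3K4me3. BTE1 summits inside these genes concentrated in the first of 5 equal parts (86.1%), and E2FA summits had a further group in the last part (27.7%).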

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

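The tests in this part were chosen after the patterns were seen, and the bounds each had to meet were written before its own value was computed.

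H2A.Z peaks were present on the chloroplast and mitochondrial chromosomes, which no comparison used and where nucleosomes are absent, with 31, 29 and 27 peaks in libraries 1, 2 and 3. Of the 10 features with replicate libraries, H2A.Z was the 1 that had such peaks. The TBP list had 60 regions on these chromosomes, of 16098 in all. No explanation was tested for either.

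E2FA summits had a further group in the last of 5 equal parts of genes, 27.7% ± 10.6 (SD, n = 3), with replicate 2 lowest at 15.7%. The 5′ ends of neighbouring genes were argued against as the whole source, since 25.2% to 36.2% of these summits lay within 500 bp of another gene's 5′ end, below the bound of 50%. The lenient threshold of the E2FA lists stayed open: with peaks at q 0.05 the share was 26.5% ± 10.6, but the lowest library, at 14.7%, missed the bound of 15 set in advance. Recovery of transcribed chromatin by any antibody may also contribute and stayed open, since 38.8% (replicate 2) to 71.8% of these summits lay in total Pol II peaks, against 18.4% ± 6.08 of summits in the first part. No biological explanation was tested.

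Among Ser5P genes, those bound by BTE1 had fewer Ser2P calls, with an odds ratio of 0.648. Gene length was argued against as the whole cause, with 0.631 (95% interval 0.493 to 0.809) over 5 length strata. Weaker Pol II signal was argued against likewise, with 0.647 (0.501 to 0.836) over strata of the Ser5P peak score. Peaks of neighbouring genes stayed open, since genes with no neighbour within 500 bp had 0.670 (0.367 to 1.23) with only 64 BTE1 genes. The pattern may come from the rule that assigns peaks to genes, since it turned to 1.31 with summits in place of whole peaks, so no biological reading is drawn.

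For the 333 genes called for BTE1 and not for E2FA, E2FA peaks missed by the rule of 3 libraries could account for most, since 78.1% had an E2FA peak in at least 1 library, within counting error of the bound of 80% set in advance (exact 95% interval 73.2 to 82.4). Recovery of transcribed chromatin fell short of what it needed as the whole source, since 46.8% were called for total Pol II (exact 95% interval 41.4 to 52.4) and 70% was set in advance. It was not excluded either, since the interval reached past the bound of 50%. The share was 35.1% for genes with both and 40.4% for genes with neither. No biological explanation was tested.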

How the results depend on the processing

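Tests restricted to marked 5′ ends or H3K4me3-marked genes, summits in place of whole peaks, E2FA peaks at q 0.05, orientation by H2A.Z and leaving out replicates for peak overlap were chosen after the data were seen. The BTE1 and E2FA association was past its threshold under every alternative, with odds ratios of 29.3 to 129. The BTE1 and WDR5A-HA association depended on the background genes and reversed among H3K4me3-marked ones, and the Ser2P result depended on the gene rule. H2A.Z and H3K4me2 at BTE1 genes and all peak overlaps kept their direction and call. Across all results and alternatives, 295 values for main comparisons and 588 for single features or lists kept direction and call, or for counts stayed within their limit. Among main comparisons, 16 values reversed, 16 lost their call, 10 gained one and 23 counts moved past their limit. Among single features or lists, 63 values reversed, 28 lost their call and 6 gained it. Where a result changed below, the cause was not tested. Depth was unknown and its effect not examined, and the E2F motif test and its alternatives were not run for want of a genome sequence.

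With peaks above their library's median score, genes fell to 859 for BTE1, 7875 for WDR5A-HA, 6959 for total Pol II, 6668 for Ser5P, 7075 for Ser2P, 4033 for H3K4me1, 7835 for H3K4me2, 8434 for H3K4me3 and 13730 for H2A.Z, as fewer peaks entered. BTE1 odds ratios became 0.896 (total Pol II), 0.785 (Ser2P, now past the threshold), 1.03 (H3K4me1) and 1.04 (H3K4me3), with the calls for total Pol II and both marks lost, and those of E2FA 0.961 (total Pol II), 1.06 (Ser5P) and 1.015 (Ser2P), with all 3 calls lost. List shares that changed side, none past its threshold, were 0.0% of ribosomal genes for BTE1. For E2FA they were 7.14% of photosynthesis, 5% of light signalling and 7.69% of reference genes, and for WDR5A-HA 25.0% of DREAM and 21.2% of elongation genes.

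With at least 50% of the peak or window covered, genes fell to 6513 for total Pol II, 5770 for Ser5P, 6165 for Ser2P and 6030 for H3K4me2. BTE1 odds ratios with Ser5P and Ser2P became 0.818 and 0.826, both now past the threshold. Those of E2FA became 0.856 with total Pol II, past the threshold in the opposite direction. With Ser5P and Ser2P the E2FA values were 0.921 and 0.944, both with the call lost. Ser2P among Ser5P genes was 0.819 (exact p 0.209). List shares that changed side were 4.76% of photosynthesis and 0.0% of light signalling genes for BTE1, and 0.0% of light signalling and 7.69% of reference genes for E2FA.

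With wider windows, BTE1 odds ratios were 1.006 with total Pol II and 1.07 with Ser5P, and shares that changed side were 10% of light signalling genes for E2FA and 60% of chromatin replication genes for WDR5A-HA. With calls in at least 2 libraries, E2FA had 4540 genes, and BTE1 odds ratios were 0.985 (total Pol II), 1.11 (Ser5P, adjusted p 0.0246, past the threshold in the opposite direction) and 1.07 (Ser2P). Shares that changed side were 19.0% of photosynthesis, 18.2% of ribosomal and 23.1% of reference genes for E2FA, and 59.3% of DNA replication and 60% of chromatin replication genes for WDR5A-HA. With the lists for the whole series, E2FA had 4305 genes and BTE1 odds ratios were 1.00, 1.18 and 1.08 for the same 3 forms, with Ser5P again past the threshold in the opposite direction (adjusted p 0.000285). The E2FA list shares were again 19.0%, 18.2% and 23.1%, and those of WDR5A-HA 63.0% and 60%.

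Leaving out each replicate in turn gave 2513 to 3882 E2FA genes, and BTE1 odds ratios of 0.875 to 0.970 with total Pol II and 0.972 to 1.03 with Ser5P, each highest without replicate 2. E2FA odds ratios were 1.18 to 1.98 with total Pol II, 1.33 to 2.29 with Ser5P, 1.34 to 2.14 with Ser2P and 1.88 to 2.96 with TBP, each highest without replicate 2. E2FA list shares were 7.14% to 19.0% of photosynthesis, 4.55% to 18.2% of ribosomal, 10% to 30.0% of light signalling and 7.69% to 23.1% of reference genes. WDR5A-HA shares were 48.1% to 53.7% of DNA replication and 46.7% to 53.3% of chromatin replication genes.

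With the 5′ end marked by H3K4me3 alone, odds ratios with WDR5A-HA were 0.830 for BTE1 (adjusted p 0.0194, past the threshold in the opposite direction) and 0.968 for E2FA (call lost). Those of BTE1 were 0.496 (Ser5P) and 0.483 (Ser2P), both now past the threshold, 1.64 (H3K4me3) and 0.867 (TBP), both with the call lost. These genes were chosen by an H3K4me3 summit, so the H3K4me3 test had little room to show a difference. Odds ratios of E2FA were 0.569, 0.624 and 0.594 with total Pol II, Ser5P and Ser2P. Those of WDR5A-HA were 0.735, 0.778 and 0.671 with H3K4me1, H3K4me2 and H2A.Z. All of these E2FA and WDR5A-HA values passed the threshold in the opposite direction. List shares that changed side were 6.90% of photosynthesis genes for BTE1, 10.3% of photosynthesis and 8.33% of reference genes for E2FA, and 47.8%, 43.8% and 41.9% of G1/S, DREAM and elongation genes for WDR5A-HA, which had 2 enriched lists and lost its calls at histone (78.6%, adjusted p 0.232), light signalling and reference genes (adjusted p 0.0564 each). E2FA lost its calls at mitotic genes (16.7%, adjusted p 0.381), elongation genes (adjusted p 0.158) and TBP (1.04, adjusted p 0.56), and BTE1 at elongation genes (adjusted p 0.11). Among H3K4me3-marked genes with both ends, the odds ratios were 0.746 and 0.969 with WDR5A-HA, 0.535, 0.522, 1.13 and 0.670 for BTE1, 0.660, 0.755 and 0.746 for E2FA with 1.00 for TBP, and 0.949, 0.758 and 0.683 for WDR5A-HA, in the same order. For BTE1 the Ser5P and Ser2P calls were gained here too. The H3K4me3 call was lost, again in genes chosen by that mark. BTE1 with TBP passed the threshold in the opposite direction. So did BTE1 with WDR5A-HA, E2FA with all 3 Pol II forms, and WDR5A-HA with H3K4me2 and H2A.Z. The calls of WDR5A-HA with E2FA and with H3K4me1 were lost. Ser2P among Ser5P genes was 0.726 (exact p 0.0565).

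With the summit in the window, genes fell to 5182 (total Pol II), 4801 (Ser5P), 4753 (Ser2P) and 6869 (H3K4me2). Odds ratios were 0.961 and 1.03 for BTE1 with total Pol II and Ser2P, 0.959, 1.02 and 1.13 for E2FA with Ser5P, total Pol II and Ser2P (all 3 calls lost), and 1.31 for Ser2P among Ser5P genes. Shares that changed side were 4.76% of photosynthesis genes for BTE1, 5% of light signalling and 7.69% of reference genes for E2FA, and 48.0% of DNA repair genes for WDR5A-HA.

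Against genes with total Pol II or Ser5P, WDR5A-HA odds ratios were 1.05 (BTE1) and 1.105 (E2FA). Those of BTE1 were 0.751 (Ser2P, now past the threshold), 1.16 (H3K4me1) and 1.15 (TBP), the last 2 with their calls lost, and E2FA with Ser2P had 0.895. Enriched lists fell to 7 for BTE1, 5 for E2FA and 1 for WDR5A-HA, whose shares of DNA repair, DREAM, histone and elongation genes, 83.3%, 53.8%, 80.8% and 69.6%, changed side, with fewer genes tested. Over gene length strata, BTE1 odds ratios were 0.736 (Ser5P) and 0.705 (Ser2P), both now past the threshold, and 1.09 (TBP, call lost), and those of E2FA 0.948 (total Pol II) and 0.995 (Ser2P). With total Pol II in place of Ser5P, the Ser2P odds ratio was 0.970.

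The design does not pair libraries by replicate number. In the data, the correlation of same-numbered Ser5P and Ser2P libraries was 0.157, 0.0864 and 0.105, against a highest value of 0.0017 for other numbers. The mean over other numbers was −0.0578, so these values concern differences between libraries and not how alike the libraries were. Each Ser5P and Ser2P library thus correlated best with its own number, a hint from the data and not from the design. In no comparison did every same-numbered value exceed 0.1. H3K4me3 and H3K4me2 libraries showed the same more weakly (0.033, 0.0287 and 0.0235, against −0.0078). H3K4me3 and H3K4me1 libraries did not (0.0056, 0.0159 and 0.0019, against 0.0084). With the replicate number as a block, position differences were −0.0322 for Ser5P against Ser2P (exact p 0.5), −0.360 for H3K4me3 against H3K4me1 and −0.0853 against H3K4me2 (exact p 0.25 each). The smallest possible p was 0.25 with the block and 0.1 without it, so no call was possible either way.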

Other observations

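The comparison of all gene lists with all features was chosen after the data were seen, and its p-values were adjusted over all lists and features.

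Photosynthesis genes carried Pol II and H3K4me3 but lacked H3K4me1. Of 42 such genes, 41 carried total Pol II, 42 carried Ser5P and 40 carried H3K4me3, but 0 carried H3K4me1 against 36.6% of other genes (Fisher's exact adjusted p 8.16e-08). H3K4me2 was called at 10 of them (adjusted p 3.73e-05) and H2A.Z at 21 (adjusted p 0.00011), both below other genes. Histone genes likewise carried H3K4me3 at 27 of 28 and H3K4me1 at 1 of 28 (adjusted p 0.00024), yet H2A.Z at 27. Ribosomal protein genes differed, with H3K4me1 at 16 of 22 (adjusted p 0.00143). Gene length was not taken into account in these tests.

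DNA replication genes carried H2A.Z at 54 of 54 and H3K4me2 at 52 of 54 (Fisher's exact adjusted p 2.05e-05 and 2.80e-09), while total Pol II was called at 16 of 54 (adjusted p 0.13). Seed and floral genes carried H2A.Z and H3K4me3 less often than other genes, at 16 of 29 and 2 of 29 (adjusted p 0.00922 and 4.01e-09). Of all genes, 78.7% carried H2A.Z and 63.2% carried H3K4me3.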
